A study of Gallus gallus with 6 samples.

How the data were processed

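Gene expression was measured by RNA sequencing of whole chicken embryos (Gallus gallus) at Hamburger-Hamilton stage 10. At this stage the cranial neural crest, a migratory cell population that forms at the edge of the neural plate, is leaving the dorsal neural tube. The labels define 2 groups of 3 libraries, control embryos and embryos treated with zinc oxide (ZnO) nanoparticles. They give no dose, route or length of exposure. The libraries are named here by group and replicate number. The labels do not say whether a replicate is 1 embryo, a pool of embryos or a repeat of the same RNA. The p-values therefore measure the spread between these samples, which may be technical in part. Levels of W-linked genes, given at the end, argue against repeats of the same RNA among controls. The stage label of each sample also carries a window of hours that starts at 34 hours and ends at 39, 40 and 41 hours for control 1, 2 and 3, and at 42, 43 and 44 hours for ZnO 1, 2 and 3. Because the end increases by 1 hour from each sample to the next, it may be an automatic fill, and it entered no fit.

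Per the labels' protocols, RNA was extracted with Trizol, 1 µg of total RNA per sample went into an Illumina TruSeq kit, and paired-end reads of 125 or 150 bp were generated on a HiSeq instrument. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1 were used, with no parameters given. The notes name mm10, a mouse build, as the only genome build. The gene identifiers in the files are NCBI gene numbers, of which 19704 of 24098 (81.8%) are chicken genes in the RefSeq table of assembly GRCg7b. That table was used for gene symbols and biotypes only, and no coordinates are given because the build behind the files is not settled. The use of strand in the counting is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart, and neither can reads that close paralogs share.

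Each deposited file holds 1 value per gene for 1 library, and the authors' values behave as FPKM, read numbers scaled to the length of the gene model and to the depth of the library. The values of a gene were whole multiples of a step that depended on its length and on the library, so whole reads had been counted. Solving these steps gave depths of 18305990, 18208501 and 19843561 reads for control 1, 2 and 3, and 18271504, 18940736 and 18544668 reads for ZnO 1, 2 and 3, a range of 1.09-fold. With these depths, all 13311 genes tested gave reads within 0.005 of a whole number in every library, searching gene lengths of 20 to 60000 bp. A deliberately wrong depth gave whole reads for 2 of 500 genes, and on simulated values 396 of 400 genes gave back their reads. The recovered reads summed to 99.5% to 99.6% of each depth. The median gene tested had 579 reads in the shallowest library by that measure and 649 in the deepest, so counting error was small beside the spread between libraries for most genes. Intervals from reads cover counting error only.

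The design fixed before the data were examined assumed a count table. Because the files hold FPKM, the test that design named for normalized values was used. Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment over all 13311 genes and a threshold of 0.05. Fold changes are ZnO minus control on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors are SD over 3 libraries for group means and SE for fold changes. With 3 against 3 libraries, the smallest p of an exact two-sided permutation test is 0.1.

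Before the data were examined, 29 gene lists were fixed for metal handling, oxidative and other stress responses, neural crest, signalling pathways, tissues of the whole embryo, HOX genes, and RNA quality and metabolism. Of 971 list entries, 885 matched by symbol and 17 by synonym. The list of mitochondrially encoded genes had under 5 measured members, and 28 lists were tested with camera from limma, with its preset correlation of 0.01, two-sided and adjusted over the lists. Each list was also tested with a correlation estimated from the data and with fry, a rotation test from limma. Where genes were adjusted over a list alone, the number of lists searched was not corrected for.

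The genes named were fixed by a rule with 3 parts. Part 1 was a set of 20 stress, metal and crest genes, of which 19 were measured and SLC30A1 was not analysed here. Part 2 was up to 10 higher and 10 lower genes past the threshold with at least 5 FPKM and groups that did not overlap, and it gave 0 genes. Part 3 was up to 4 members with the smallest p in each list described. Other genes are said to have been chosen after their values were seen. A gene that part 3 selects is not reported here.

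The test was checked on simulated data for the comparison of ZnO with control, with 200 genes changed in each of 5 simulations over 13311 genes and independent noise of the size seen here. It recovered 3.9% of genes changed 1.5-fold, 43% of those changed 2-fold and 87.6% of those changed 4-fold, with 23 false calls among 469. A list shifted by -0.4 on the log2 scale was called in 5 of 5 simulations, with 0 calls of other lists. Genes in these simulations varied independently, unlike genes in the libraries. The noise sizes were shuffled between genes, which breaks their tie to expression level. Changed genes were drawn only from those with higher values, so recovery of low genes was not measured.

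Alternatives fixed in advance were median-of-ratios and upper-quartile scaling, a pseudocount of 0.1, no filter on low values, a filter of at least 1 FPKM in 3 libraries, the replicate number as a block, and leaving out each library. For the similarity of libraries, a pseudocount of 0.5 and the 500 most variable genes were tried. Alternatives added after the data were seen were limma-voom on the recovered reads, with and without sample weights, the first residual component (the main direction of variation left after the group means) as a covariate in either fit, and protein-coding genes alone. Planned fits that need deposited counts were left out. The interval of a difference between sets of HOX genes came from 10000 bootstrap draws of genes. Values were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.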

Results

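The transcriptome of whole stage 10 chicken embryos was measured in 3 control libraries and in 3 libraries of embryos exposed to zinc oxide nanoparticles, particles that can release zinc ions. The title of the series concerns cranial neural crest development and oxidant stress, and the comparison asks which genes differ between treated and control embryos. The depth behind the values, computed from the FPKM steps, was 18208501 to 19843561 reads per library, and 18924 to 19347 genes had a value above 0.

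The libraries resembled each other closely, with Pearson correlations of log2(FPKM + 1) across genes from 0.945 to 0.985. The largest difference between libraries did not follow the treatment. The first principal component held 50.8% of the variance and set ZnO 1 (-36.3) and control 2 (-23.4) apart from control 3 (16), ZnO 2 (17.5) and ZnO 3 (28.9), with control 1 between them (-2.61). The second held 20.6% and separated the groups, with controls at 13.3 to 15.3 and treated libraries at -20.3 to -6.83. ZnO 1 correlated less with ZnO 2 (0.959) and ZnO 3 (0.945) than with control 2 (0.976). The mean level of cytosolic ribosomal protein genes in ZnO 1 was -0.57 on the log2 scale relative to the mean of the libraries, against -0.05 to 0.32 in the others. The FPKM of ZnO 1 summed to 480047, against 531480 to 559992 in the others at like depth. Its reads therefore lay on longer gene models on average. Whether this shift and the ribosomal level share a cause was not tested.

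**Figure D1:**
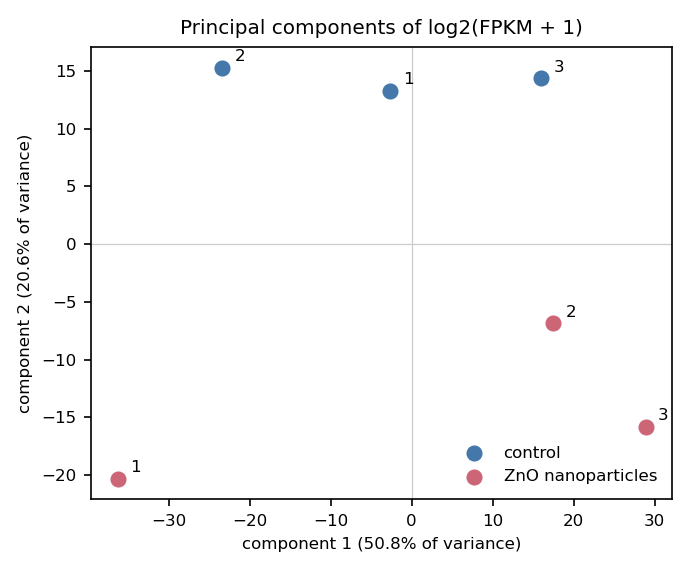
Each point is 1 library (blue, control; red, ZnO nanoparticles), numbered by replicate, placed by its first (x axis, 50.8% of variance) and second (y axis, 20.6%) principal component of log2(FPKM + 1). The 3 controls lie at 13.3 to 15.3 on the second component and the 3 treated libraries at -20.3 to -6.83, while the first component spreads both groups.

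No gene passed the threshold between treated and control embryos. Of 13311 genes tested with limma, 0 had an adjusted p under 0.05, and the lowest adjusted p was 0.606. At an unadjusted p under 0.05 there were 754 genes, 407 higher and 347 lower in treated embryos, where 666 would be reached with no effect. All 3 treated libraries lay above or below all 3 controls for 1529 genes (11.5%), where chance gives 10%. limma-voom on the recovered reads also gave 0 genes. In fits chosen after the data were seen, 23 genes passed with the first residual component as covariate, 700 with that component in limma-voom and 742 with sample weights in limma-voom. The component was taken from the residuals of the same comparison, which lowers the error of the test by construction. The unadjusted count was 396 without control 1, 414 without control 2 and 1948 without ZnO 1. Without ZnO 1, 4 genes passed, namely MT4 and MT3, the small heat shock protein gene HSPB9, and the gene with ID 100498692, which the name table did not match and which was listed at 0 FPKM in ZnO 2 and ZnO 3 against 3.88 to 7.39 FPKM in the controls.

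Metallothionein transcripts, which encode small proteins that bind zinc and other metals, were several times more abundant in ZnO 2 and ZnO 3 than in any other library. MT4 (gene ID 396212) stood at 211, 187 and 167 FPKM in the controls and at 860 and 1136 FPKM in ZnO 2 and ZnO 3, but at 177 FPKM in ZnO 1. MT3 (gene ID 770592) stood at 91.0, 74.9 and 90.3 FPKM in the controls, 332 and 516 FPKM in ZnO 2 and ZnO 3, and 83.2 FPKM in ZnO 1. Over all libraries neither gene passed (MT4 log2 fold change 1.57 ± 0.61 SE, adjusted p = 0.861; MT3 1.5 ± 0.58 SE, adjusted p = 0.861). Without ZnO 1, the log2 fold changes were 2.39 for MT4 (adjusted p = 0.0128) and 2.27 for MT3 (adjusted p = 0.0314). ZnO 1 is the treated library at the control level, so leaving it out raises both by construction. Without any other library, the adjusted p of both was 0.911 or more in limma. The genes are paralogs whose reads the counting could have divided between them. In the list of zinc and metal handling genes, 14 of 22 measured members were higher and 8 lower, with a mean log2 fold change of 0.24 (0.15 without control 3, and 0.24 without ZnO 1). The median was 0.14. MT3 and MT4 are members and raised the mean, more so without ZnO 1, so it does not describe a rise shared by the list. TFRC, the transferrin receptor that takes up iron, was at 29.6 ± 5.50 FPKM (SD, n = 3) in controls and 43.5 ± 8.18 FPKM in treated embryos, and the copper transporter gene ATP7B at 1.56 ± 0.355 and 2.37 ± 0.532 FPKM. None of the 22 passed over all genes and 0 when adjusted over the list alone. The list was called higher by camera (adjusted p = 0.0324), but not with an estimated correlation (adjusted p = 0.786) nor without control 3, ZnO 1 or ZnO 3 (adjusted p = 0.354, 0.107 and 0.0736).

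No gene of the NRF2 target or antioxidant enzyme lists passed. On simulated data, 3.9% of genes changed 1.5-fold were recovered, so differences of that size would mostly be missed if these genes varied as the simulated ones did. HMOX1, which encodes haem oxygenase, had 13.4 ± 0.857 FPKM in controls and 15.7 ± 4.23 FPKM in treated embryos (SD, n = 3), a log2 fold change of 0.18 with a 95% interval of -0.26 to 0.62. NQO1, a quinone reductase gene, had 10.4 ± 0.953 and 11.6 ± 1.27 FPKM (log2 fold change 0.14, interval -0.19 to 0.47). The intervals of the superoxide dismutase genes SOD1 (-0.56 to 0.55) and SOD2 (-0.63 to 0.45), of catalase CAT (-0.53 to 0.57) and of the glutathione peroxidase gene GPX1 (-0.57 to 0.62) all included 0, with adjusted p between 0.980 and 0.999 in limma. Of 21 measured targets of NRF2, the transcription factor that answers oxidants, 12 were higher and 9 lower. They included FECH (14.1 ± 1.24 against 25.5 ± 11.4 FPKM) and the cystine carrier gene SLC7A11 (12.9 ± 2.36 against 8.61 ± 2.99 FPKM). Of 27 antioxidant enzyme genes, 6 were higher and 21 lower, among them GPX7 (36.0 ± 6.92 against 25.5 ± 3.39 FPKM) and GPX8 (21.5 ± 6.59 against 13.2 ± 2.75 FPKM). Neither list was called (adjusted p = 0.433 for NRF2 targets and 0.150 for antioxidant enzymes), and 0 members of either passed, over all genes or when adjusted over the list alone. The antioxidant list had a mean level of -0.30 in ZnO 1, against 0.01 to 0.11 in the other libraries. It was called lower without ZnO 3 (adjusted p = 0.00824), while without ZnO 1 its direction turned up (adjusted p = 0.675).

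Among heat shock genes, HSPB9 (gene ID 428310) had 27.0, 22.1 and 37.0 FPKM in controls and 54.6, 149 and 122 FPKM in treated embryos, a 3.78-fold difference of means (log2 fold change 1.79 ± 0.37 SE). Its adjusted p was 0.746 over all genes and 0.0317 when adjusted over the list alone, the 1 member of 26 to pass in that way. The latter was 0.145 without control 1, 0.135 without control 2, 0.111 without ZnO 2 and 0.12 without ZnO 3. HSPA2 (66.4 ± 14.3 against 99.5 ± 14.2 FPKM) and the co-chaperone gene DNAJB1 (23.9 ± 1.98 against 31.0 ± 0.789 FPKM) were higher in each treated library, and HSPB1 was lower in each (85.8 ± 4.43 against 66.6 ± 6.71 FPKM), none of them past the threshold. The list as a whole was not called (camera adjusted p = 0.145), but was called higher without control 3 (adjusted p = 0.0162) or ZnO 1 (adjusted p = 0.000457).

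The neural crest list split evenly, with 17 of 34 measured border and specifier genes higher and 17 lower, and it was not called (camera adjusted p = 0.613; 0.0434, higher, without control 3). SNAI2 (gene ID 432368), a zinc finger repressor that takes part in the release of crest cells from the neural tube, was lower in each treated library. It had 34.9, 33.2 and 37.0 FPKM in controls and 21.9, 20.6 and 23.5 FPKM in treated embryos, a log2 fold change of -0.65 ± 0.14 SE with an interval of -0.96 to -0.34. Each library had 835 or more SNAI2 reads. Its adjusted p was 0.746 over all genes and 0.0466 when adjusted over the list alone, where it was the only member to pass. The latter was 0.306, 0.149 and 0.141 without control 1, 2 and 3, and 0.0138, 0.16 and 0.0516 without ZnO 1, 2 and 3. An exact permutation test gave p = 0.1, the smallest possible.

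Other crest regulators lay in both directions, and their difference from SNAI2 was not tested. FOXD3 had 28.1 ± 1.38 FPKM in controls and 38.2 ± 9.86 FPKM in treated embryos (SD, n = 3), higher in each treated library, with an interval of the log2 fold change of -0.05 to 0.85. MSX1 had 190.3 ± 18.1 and 154 ± 19.7 FPKM, lower in each treated library. PAX7 (1.96 ± 0.407 and 2.34 ± 1.03 FPKM), TFAP2A (23.6 ± 4.98 and 24.8 ± 2.58 FPKM), SOX9 (14.7 ± 1.93 and 15.4 ± 2.79 FPKM), SOX10 (9.24 ± 0.651 and 8.22 ± 2.67 FPKM) and ETS1 (52.7 ± 7.83 and 49.6 ± 5.50 FPKM) overlapped between groups. DLX6 (8.95 ± 1.48 and 14.4 ± 3.57 FPKM) and PRDM1 (6.99 ± 1.56 and 9.60 ± 0.299 FPKM) were among the members with the smallest p. Of 43 genes of crest migration and adhesion, 20 were higher and 23 lower, 0 passed, and the list was not called (adjusted p = 0.695). Without ZnO 1 that list was called lower (adjusted p = 0.0303). The cadherin genes CDH1 (52.0 ± 8.17 and 72.8 ± 21.4 FPKM), CDH2 (101 ± 31.6 and 88.1 ± 33.7 FPKM) and CDH6 (7.49 ± 1.78 and 7.01 ± 1.81 FPKM) overlapped between groups, as did the endothelin receptor gene EDNRA (7.23 ± 1.82 and 4.25 ± 1.75 FPKM).

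**Figure D2:**
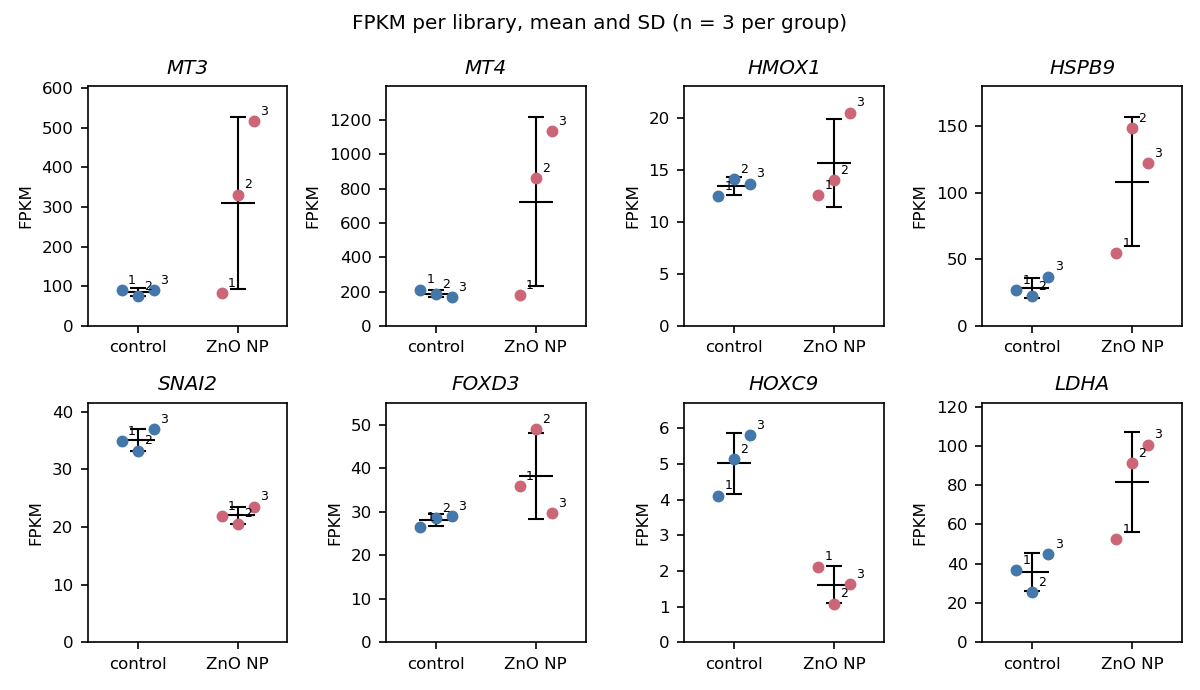
FPKM (y axis, linear, from 0) of 8 genes in each library (blue, control; red, ZnO nanoparticles; numbers are replicates), with group mean and SD (n = 3). MT3 and MT4 are high in ZnO 2 and 3 and near 83.2 and 177 FPKM in ZnO 1, SNAI2 and HOXC9 are lower in each treated library, and HSPB9, FOXD3 and LDHA are higher in each.

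Of 25 measured members of the list of HOX genes, which mark position along the trunk, 22 were lower in treated embryos, with a mean log2 fold change of -0.40 (camera adjusted p = 1.74e-09, and adjusted p = 0.465 with an estimated correlation). Relative to the mean of the libraries, the mean level of the list was 0.10, 0.26 and 0.24 in control 1, 2 and 3, -0.37 in ZnO 1 and -0.33 in ZnO 2, but 0.10 in ZnO 3, the level of control 1. The list holds 3 CDX genes, and 21 of the 22 HOX genes proper were lower. HOXC9 (gene ID 425723) had 5.02 ± 0.856 FPKM in controls and 1.62 ± 0.518 FPKM in treated embryos (log2 fold change -1.21 ± 0.20 SE). Its adjusted p over all genes was 0.606. It passed when adjusted over the list alone (adjusted p = 0.0073), where it was the only member to pass, and stayed under 0.05 without any one library. HOXC9 had only 17 to 95 reads per library, so counting error weighs more on it than on most genes. HOXB2 (7.99 ± 1.13 and 4.90 ± 0.459 FPKM), HOXA4 (33.0 ± 4.97 and 22.1 ± 1.77 FPKM) and HOXB5 (41.2 ± 2.30 and 27.0 ± 5.54 FPKM) were lower in each treated library. The stage windows in the labels end at 39 to 41 hours for controls and at 42 to 44 hours for treated embryos. These ends increase by exactly 1 hour from each library to the next in the order of the labels, as an automatic fill of a spreadsheet would give, so whether they are measured ages is not settled. If they are, age and treatment are not separated by the design.

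Lists of mesoderm derivatives were also called lower by camera with its preset correlation. Of 20 genes of paraxial mesoderm, somites and muscle, 17 were lower (mean log2 fold change -0.31, camera adjusted p = 0.00013, and adjusted p = 0.465 with an estimated correlation). MEOX1 (21.5 ± 2.11 and 14.1 ± 3.58 FPKM) and TCF15 (50.6 ± 7.23 and 34.1 ± 7.24 FPKM), both regulators of somites, and OSR1 (6.53 ± 0.562 and 4.02 ± 0.964 FPKM) were lower in each treated library. Of 31 heart muscle genes, 26 were lower (mean log2 fold change -0.26, camera adjusted p = 8.7e-06, and adjusted p = 0.465 with an estimated correlation). They included the cardiac transcription factor gene NKX2-5 (51.8 ± 0.721 and 37.4 ± 5.48 FPKM), its relative NKX2-6 (11.1 ± 1.42 and 7.69 ± 0.583 FPKM) and MYOCD (7.88 ± 0.526 and 5.64 ± 0.517 FPKM). The mean level of the heart muscle list was 0.04 in ZnO 1, near control 3 at 0.06, and -0.18 and -0.24 in ZnO 2 and ZnO 3. In the BMP and TGF-beta signalling list, 24 of 29 genes were lower, including SMAD6 (133 ± 7.87 and 98.3 ± 20.3 FPKM) and TGFB2 (8.94 ± 0.439 and 5.72 ± 1.83 FPKM). That list was called lower by camera (adjusted p = 0.0237), but not with an estimated correlation (adjusted p = 0.812) nor without control 2, ZnO 2 or ZnO 3 (adjusted p = 0.188, 0.0772 and 0.538). No member of these 3 lists passed over all genes, and 0 when adjusted over the list alone.

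Of 28 measured neural tube and brain genes, 20 had higher means in treated embryos (mean log2 fold change 0.27, camera adjusted p = 5.2e-06, and adjusted p = 0.702 with an estimated correlation). The groups overlapped in the mean level of this list, which was -0.13 in ZnO 3, below control 3 at 0.12, against 0.32 and 0.22 in ZnO 1 and ZnO 2 and -0.22 and -0.31 in control 1 and control 2. The forebrain and eye field gene SIX3 had 20.5 ± 7.94 FPKM in controls and 40.2 ± 8.96 FPKM in treated embryos, and LHX2 had 1.05 ± 0.517 and 2.56 ± 0.354 FPKM, both higher in every treated library. Of these 28 genes, 0 passed over all genes and 0 when adjusted over the list alone.

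Among metabolic genes, 27 of 33 hypoxia and glycolysis genes were higher (mean log2 fold change 0.25, camera adjusted p = 5.34e-07, and adjusted p = 0.465 with an estimated correlation). LDHA (gene ID 396221), the lactate dehydrogenase gene, had 35.7 ± 9.67 FPKM in controls and 81.4 ± 25.5 FPKM in treated embryos, a 2.28-fold difference of means (log2 fold change 1.15 ± 0.29 SE, adjusted p = 0.782). The glucose transporter gene SLC2A14 (22.6 ± 5.44 and 38.1 ± 8.11 FPKM), the collagen hydroxylase gene P4HA1 (16.4 ± 1.28 and 24.0 ± 4.24 FPKM) and EGLN3 (1.96 ± 0.275 and 3.68 ± 1.15 FPKM) were higher in each treated library. Of 28 genes of sterol and lipid synthesis, 23 were lower, including FDFT1 (54.2 ± 2.77 and 38.1 ± 4.47 FPKM), FDPS (148 ± 16.8 and 103 ± 6.65 FPKM) and HMGCS1 (53.4 ± 3.54 and 36.3 ± 6.83 FPKM). That list was called lower by camera (adjusted p = 0.000715), but not with an estimated correlation (adjusted p = 0.702) nor without ZnO 2 (adjusted p = 0.0853). In both lists 0 members passed over all genes and 0 when adjusted over the list alone.

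All 65 cytosolic ribosomal protein genes and 44 of 49 nuclear genes of oxidative phosphorylation had lower means in treated embryos (mean log2 fold changes -0.24 and -0.18, camera adjusted p = 1.68e-07 and 0.000202). Neither call held with an estimated correlation (adjusted p = 0.812 for both) or without ZnO 1 (adjusted p = 0.884 and 0.675), where the mean log2 fold changes were -0.02 and 0.01. Examples were RPL17 (log2 fold change -0.48 ± 0.23 SE) and COX6A1 (-0.40 ± 0.17 SE). In both lists 0 members passed, over all genes or when adjusted over the list alone.

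Immediate early and inflammatory genes were higher for 22 of 29 (mean log2 fold change 0.12, camera adjusted p = 0.0324, and adjusted p = 0.465 with an estimated correlation), with EGR3 at 3.74 ± 0.844 and 5.36 ± 1.41 FPKM and 0 members past the threshold, over all genes or when adjusted over the list alone. That call was lost without control 1, control 2, ZnO 1 or ZnO 2 (adjusted p = 0.0703, 0.0945, 0.185 and 0.0853), and with a filter of at least 1 FPKM in 3 libraries (adjusted p = 0.083). In the integrated stress response list, which was not called (adjusted p = 0.735), PCK2 (66.1 ± 4.01 and 124 ± 30.6 FPKM) and DDIT4 (227 ± 9.62 and 330.1 ± 68.6 FPKM) were higher in each treated library, while ASNS overlapped (65.2 ± 10.4 and 49.8 ± 24.5 FPKM).

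The remaining lists were not called, with camera adjusted p of 0.420 for the unfolded protein response, 0.696 for p53 targets and apoptosis, 0.197 for WNT, 0.8 for FGF and 0.229 for SHH signalling, and 0.974 for retinoic acid and the somite clock. The adjusted p was 0.193 for placode and surface ectoderm, 0.0939 for blood and endothelium, 0.0929 for endoderm and yolk sac, 0.499 for notochord and axial mesoderm and 0.297 for the cell cycle. Leaving out 1 library gave calls for some of them: higher for blood and endothelium without control 1 or ZnO 2 (adjusted p = 0.00938 and 0.0102), for endoderm and yolk sac without control 2 or ZnO 2 (0.000249 and 2.65e-05), and for placode and surface ectoderm without control 3 (0.0162). WNT and SHH signalling were called higher without control 2 (adjusted p = 0.0379 and 0.0294) or ZnO 3 (0.035 and 0.00367), the cell cycle higher without ZnO 1 (0.0196), and the unfolded protein response lower without control 3 or ZnO 1 (0.0126 and 0.00106). For the integrated stress, crest migration and retinoic acid lists the mean was below 0 while camera, which compares a list with all other genes, gave the direction as up, and the median of the crest specifier list was likewise below 0 with a mean above it. In all, camera called 11 of 28 lists, 4 higher and 7 lower, with the preset correlation. With an estimated correlation 0 were called, and fry called 0 for one direction and 0 for either. Every division of the 6 libraries into 3 and 3 gave 7 to 17 called lists with the preset correlation. The number of such calls therefore does not set the treatment apart from other divisions.

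**Figure D3:**
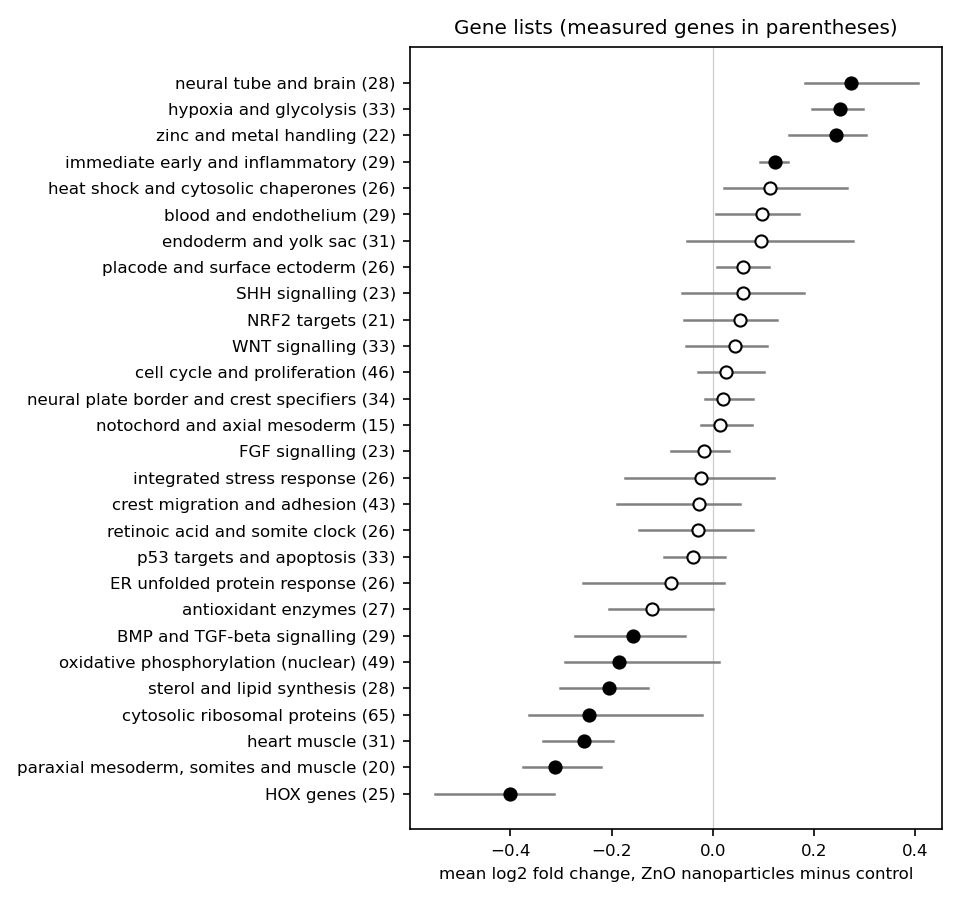
Mean log2 fold change of each gene list (x axis, ZnO nanoparticles minus control on the log2(FPKM + 1) scale), with the number of measured genes in parentheses. Filled points are the 11 lists called by camera with its preset correlation, and bars span the means obtained when each of the 6 libraries was left out, so that the ribosomal list reaches -0.02 without ZnO 1.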

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

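The fits with recovered reads, with the first residual component, with sample weights and with protein-coding genes alone were chosen after the data were seen. The count of 0 genes past the threshold was the same with both scalings, both filters, a pseudocount of 0.1, protein-coding genes, limma-voom on recovered reads and each library left out but ZnO 1 (4 genes; range 0 to 4). It was 23 with the first residual component as covariate, 700 with that component in limma-voom on recovered reads and 742 with sample weights in limma-voom. Genes with unadjusted p under 0.05 numbered 754, 1153 without a filter on low values, where 21281 genes were tested, and 396 to 1948 with 1 library left out. With the component they numbered 2792, with the component in limma-voom 3008 and with sample weights 3352; the cause was not tested. The count of 11 lists became 0 with an estimated correlation and 0 with fry, was 10 with the filter of 1 FPKM in 3 libraries (the immediate early list lost its call, adjusted p = 0.083), and ranged from 10 to 14 with 1 library left out. The lowest correlation between libraries, 0.945, was 0.717 over the 500 most variable genes, which are those that differ most. With the replicate block, 0 genes passed (758 at an unadjusted p under 0.05) and 11 lists were called. Deviations of libraries with the same number correlated at -0.03, -0.37 and 0.41, and 0 of the 3 controls correlated best with the treated library of its own number, so the numbers were not taken to pair the samples. For control 3 this was nearly a tie (0.42 with ZnO 2). Control 2 correlated best with ZnO 1 (0.58), which lay on the same side of the first component. The check therefore cannot exclude a batch shared by number.

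Of 1411 values of 83 genes under alternatives, 1282 kept their direction and side of the threshold, 103 passed only there and 26 changed sign. Most of the 83 genes were chosen for a small p in these same data, and 0 passed in the main fit. Most values therefore keep direction and side by selection, and the counts do not measure stability. With 1 library left out, 12 genes changed sign in 21 values, and all 12 were among the 19 measured genes of part 1. Their log2 fold changes then ranged from -0.01 to 0.32 for HMOX1, -0.14 to 0.22 for SOD1, -0.24 to 0.18 for SOD2, -0.20 to 0.28 for CAT, -0.13 to 0.28 for GPX1, -0.03 to 0.42 for PAX7, -0.02 to 0.24 for TFAP2A, -0.07 to 0.16 for SOX9, -0.38 to 0.06 for SOX10, -0.19 to 0.02 for ETS1, -0.51 to 0 for CDH2 and -0.27 to 0.08 for CDH6. SOD1 was 0.01 with either scaling, and sample weights gave 0.16 for SOD1, 0.12 for SOD2 and -0.13 for SOX9. Of 308 list values, 255 kept their side of the threshold, 35 lost the call and 16 gained it with the direction kept, and 2 changed both side and direction. The direction also changed in 23 that were called in neither fit. Without ZnO 1 it changed for 8 lists. Of these, crest migration became called lower (adjusted p = 0.0303; 0.0813 to 0.653 without another library) and oxidative phosphorylation lost its call (0.675; 2.28e-09 to 0.0276 without another library); the cause was not tested. The other 6, called neither there nor with all libraries, were antioxidant enzymes and p53 targets, then up, and WNT, SHH, retinoic acid and endoderm, then down. Planned count models were not run because the deposited values are FPKM. At this depth the median gene had 579 or more reads, so the spread between libraries limits the calls.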

Other observations

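Apart from the planned limma, camera and fry results that it repeats, the tests in this part were chosen after the values were seen. So were the genes in it that the lists do not hold. Several genes outside the lists were among those with the smallest p. Their groups did not overlap, which choosing genes by a small p favours by itself. None of them passed over all genes (adjusted p from 0.606 to 0.639 in limma). The nucleotide receptor gene P2RY6 had 1.26 ± 0.238 FPKM in controls and 3.86 ± 0.404 FPKM in treated embryos (SD, n = 3), ZBTB32 had 7.40 ± 1.28 and 15.2 ± 0.115 FPKM, and the protease inhibitor gene TIMP3 had 17.6 ± 3.72 and 35.4 ± 4.58 FPKM. The collagen cross-linking enzyme gene LOX had 1.61 ± 0.167 and 3.99 ± 0.767 FPKM. Lower in treated embryos were the annexin gene ANXA1 (49.8 ± 0.252 and 27.4 ± 1.90 FPKM) and the growth factor gene FGF7 (2.46 ± 0.178 and 0.886 ± 0.107 FPKM). P2RY6, LOX and FGF7 had only 24 to 90, 34 to 105 and 24 to 81 reads per library, so counting error weighs more on them. From the retinoic acid list, ALDH1A2, which encodes an enzyme that makes retinoic acid in the trunk, had 25.8 ± 3.13 and 16.3 ± 1.99 FPKM (adjusted p = 0.782).

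With the first residual component as covariate, 23 genes passed in limma, 14 higher and 9 lower, and 20 of them also passed in limma-voom with that component. Both fits share the component, which was taken from the residuals of the comparison, so that it lowers the error by construction (LDHA SE from 0.29 to 0.08 at a log2 fold change of 1.15 in both), and their shared calls are not independent evidence. LDHA led them (adjusted p = 0.0147), with HSPB9 (adjusted p = 0.0147), ANXA1 (adjusted p = 0.0252) and the monocarboxylate carrier gene SLC16A3 (29.9 ± 2.12 and 51.7 ± 13.4 FPKM, adjusted p = 0.0392). LUM, the lumican gene, was lower (103 ± 22.9 and 62.7 ± 25.7 FPKM, adjusted p = 0.0252). The 700 genes of the limma-voom fit, 343 higher and 357 lower, were 5.26% of the 13311 genes tested. Among them, 28 of 65 cytosolic ribosomal protein genes were lower and 0 higher, although the camera call of that list was lost without ZnO 1 (adjusted p = 0.884). Of 33 hypoxia and glycolysis genes 14 were higher and 0 lower, and of 22 zinc and metal genes 4 were higher and 0 lower. Lower were 11 of 31 heart muscle genes, 6 of 20 somite genes, 7 of 28 sterol genes and 7 of 49 genes of oxidative phosphorylation, with 0 higher in each list, as were 5 of 25 HOX genes and 4 of 29 BMP and TGF-beta genes. The neural tube list had 6 of 28 higher and 1 lower, crest migration 1 of 43 higher and 5 lower, and the immediate early list, which camera called higher, 0 of 29 in either direction. The overlap of these lists with the 700 genes was not tested.

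The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. A count of 0 is reached by all 10 whatever the data, so nothing can be read from the splits for the 0 genes of the real division (highest other 1), its 0 lists with an estimated correlation (highest other 1) or its 0 genes in limma-voom on recovered reads (highest other 1164). Of the 10, 3 gave at least its 754 genes at an unadjusted p under 0.05 (highest other 4130). For lists called with the preset correlation, 6 gave at least its 11 (highest other 17, lowest other 7). For the 23 genes with the component, 2 did (highest other 2969). In limma-voom on recovered reads, 2 gave at least the 700 genes with the component (highest other 3926) and 3 at least the 742 genes with sample weights (highest other 4700). The highest other counts of 4130, 2969, 1164, 3926 and 4700 genes came from setting control 1, control 2 and ZnO 1 against the rest. Setting control 1, ZnO 2 and ZnO 3 against the rest gave 3227 genes with sample weights, but 0 in the other 2 limma-voom fits. Counts several times the real one point to structure among the samples that the labels do not name, and more than 1 division gave such a count.

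MT3 and MT4 were high in ZnO 2 and ZnO 3 and near the control level in ZnO 1. The first component, which separates libraries inside both groups, would need MT4 to differ by 1.62 on the log2 scale between control 3 and control 2, and it differed by -0.16 (MT3 by 0.27, where 1.59 would be needed), which argues against that component alone. A control library under a treated label remains open for ZnO 1. Over the 200 genes of smallest p without it, ZnO 1 lay at 0.16 between the controls (0) and the other treated libraries (1), below held-out controls (0.25 to 0.50). Held out in the same way, ZnO 2 and ZnO 3 lay at only 0.54 and 0.63, near control 3 at 0.50. This position barely separates the groups, so it cannot decide the label. The mean HOX level of ZnO 1 was the lowest of the 6 libraries. On the second principal component, which was computed with ZnO 1 included, ZnO 1 lay at -20.3, farther from the controls (13.3 to 15.3) than ZnO 2 (-6.83) and ZnO 3 (-15.8). A difference in zinc dose or uptake between samples was not tested and may also account for the MT3 and MT4 levels of ZnO 1.

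The HOX, somite and heart muscle lists were called lower and the neural tube list higher by camera with its preset correlation, but 0 of these 4 with an estimated correlation (adjusted p = 0.465 for the first 3 and 0.702 for the last) or with fry, and ZnO 3 lay among or at the level of controls for the neural and HOX lists, so the pattern itself is not secure. Loss of the tail end would lower tail bud genes if the tail bud were their main source. Of 13 such genes, 11 were higher (median log2 fold change 0.23, SD 0.35, against -0.44 for the HOX list, which shares 3 of the 13). That argues against such a loss only for genes expressed mainly in the tail bud. Whole embryos cannot show how much of each gene came from other tissues. A smaller share of trunk tissue with the tail bud kept also remains open. Removing the trend with gene length and expression level left the mean of the HOX list at -0.36 (before, -0.40), of somites at -0.29, of heart muscle at -0.21 and of the neural list at 0.30, so that trend is not the whole cause. The windows in the labels, if they are ages, end later for treated embryos and so speak against a younger age of these, but they are not settled as ages, and a younger age may contribute and cannot be told apart from treatment, since the 10 HOX genes of groups 6 to 13 differed from the 12 of groups 1 to 5 by -0.18 (medians -0.53 and -0.35), with a 95% bootstrap interval over genes, which are not independent, of -0.33 to 0.02. No test set an effect of the treatment itself apart from these, and it also remains open.

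SNAI2 was lower in each treated library while other crest genes lay in both directions. A loss of crest cells as large as the SNAI2 difference would lower other crest genes by a similar amount if crest were their main source. The median of 12 of them was -0.07 (SD 0.20, with 7 lower and 0 as low as SNAI2 at -0.65). That argues against a loss of that size only for genes expressed mainly in crest, and leaves a smaller one open. Whole embryos cannot show how much of each gene came from other tissues, which could hide a loss. In the lists fixed beforehand, 0 of the 33 other crest specifier genes and 1 of 43 migration genes, EDNRA at -0.67, were as low as SNAI2 (list medians without it 0.02 and -0.02), although the migration list was called lower without ZnO 1 (adjusted p = 0.0303). Counting error is too small, since the 95% exact binomial interval of the log2 ratio of pooled reads (4232 in controls, 2626 in treated embryos) was -0.74 to -0.60. In which cells SNAI2 was lower was not tested, since whole embryos were measured, and its adjusted p over all genes was 0.746.

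The W-linked genes HINTW (532, 244 and 813 FPKM in controls, 434, 717 and 558 FPKM in treated embryos) and ATP5F1AW (41.8, 21.2 and 59.1 FPKM, then 37.0, 66.6 and 54.2 FPKM) were detected in all 6 libraries. For both, control 2 was lowest, followed by ZnO 1 and control 1. The same libraries were lowest on the first principal component (-23.4, -36.3 and -2.61). Set against the rest, they gave the highest other counts of genes above. A link between the W-linked genes and that division was not tested. HINTW had 5402 or more reads in each library, so counting error is too small for its spread among controls. Repeats of the same RNA would give like levels, so the values of both genes argue against such repeats among controls. They do not tell 1 embryo from a pool.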
